A study of Mus musculus with 13 samples.

How the data were processed

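Liver RNA of 13 male B6C3F1 mice was measured on Illumina bead arrays, 1 array per mouse. Per the labels' protocols, the tissue was archived frozen liver and biotin-labelled cRNA was hybridised. Group membership was taken from the labels. There were 4 control mice, 4 mice given dichloroacetic acid (DCA) and 5 mice given phenobarbital (PB). Replicate numbers within a group only name the arrays and pair nothing across groups.

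The main table held the intensity of each gene on a linear scale and a detection p-value for it on each array, as the authors deposited them from GenomeStudio (per the submitters' processing notes, version not given in the sources used here). It has 1 row per gene and 18138 rows, so probes of a gene had been averaged before deposit and cannot be tested one by one. A second table held 18110 of these genes as intensity values that the authors had normalized. Set against the raw columns, the lowest rank correlation of a column with its own array was 0.9996, its values lay on a linear scale, and its column medians were nearly equal. The exact normalization steps behind it stay unknown. This second table was used as an alternative.

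Of the 18138 gene names, 14307 were current symbols in the gene table of assembly GRCm38.p6, 2927 were older synonyms and 904 had no match. The names in the text are those of the deposited table. In the table, 22 names had been turned into dates or numbers by spreadsheet software and were restored from the definition column where it gave a symbol. No genome build is named for the arrays, so no coordinates are given.

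Background was corrected with limma's normexp model from the detection p-values (offset 16), followed by quantile normalization and log2, which is the procedure called neqc. In 1 step this departed from the standard procedure. In 4470 rows the detection p-value was a combination over several probes, which the standard fit cannot read. Fitted on all rows, the background SD of the arrays came out at 57.3 to 150 intensity units, against 4.32 to 12.2 when fitted on the 13668 rows of single probes. The fit on single-probe rows was therefore used. This was decided from the noise estimates before any gene was tested, but after the files had been looked at, and it changes the number of calls, so counts from the standard fit stand beside the main ones in the results. A design fixed before the data were examined had assumed a table of probes, with the brightest probe taken for each gene. That step had no use here.

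Genes with a detection p-value under 0.05 on at least 4 arrays were tested, 8431 in all (46.5%). Because of this filter 45 genes with a mean raw intensity over 300 were left out, since combined detection p-values can be high for bright genes. A model of group means was fitted to all 13 arrays with lmFit and eBayes of limma, version 3.58.1, in R 4.3.3. Each pair of groups was compared, and an F test asked for any difference among the groups. All tests were two-sided unless stated, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Errors of log2 differences are standard errors of the fit, and group values are means ± SD over arrays.

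Before the data were examined, 48 gene lists and 25 single genes were fixed, from textbook knowledge of liver, of both chemicals and of other cell types in a liver piece. The 44 lists with at least 5 tested genes were compared with all other genes by camera with its preset correlation between genes of 0.01. Beside it, camera was run with a correlation estimated for each list, as were fry (its directional and its mixed test) and an exact permutation test of the list's mean per array. The limma p-values of a list's genes were also adjusted over the list alone. That adjustment does not allow for the number of lists looked at, so genes that pass only there are not called. Other splits of the same arrays were put through the same fit, all 35 for DCA against control and 100 drawn ones for each other result. For the response shared by both treatments, 1000 sets of unchanged groups were drawn from scaled residuals of the arrays. Distances of arrays from their group centre were compared by exact permutation tests.

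The rule for the genes that are named was also fixed beforehand. In each comparison it takes up to 10 genes per direction with the largest log2 difference among those past the threshold whose groups do not overlap on any array, fills free places with the genes of smallest unadjusted p, which are given as values, and adds up to 4 members of each list described and the tested genes among the 25. The text prints part of these and counts the rest, and some genes that the rule takes are not reported here. Exceptions are said to have been chosen after their values were seen.

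Simulated data for each comparison had genes that varied independently, with 67 changed by 0.5, 67 by 1 and 66 by 2. The fit was tested on these data. It recovered 22.4% of changes of 0.5 on the log2 scale, 73.1% of changes of 1 and 97.0% of changes of 2 for DCA against control. For PB against control it recovered 22.4%, 76.1% and 98.5%. For DCA against PB it recovered 32.8%, 65.7% and 98.5%. Genes that had not been changed made up 11 of 139 calls for DCA against control and 7 of 138 calls for each other comparison. The list test called 0 of 44 lists when no list had been shifted. Genes on real arrays vary together, which the simulation leaves out. Recovery also depends on the number of changed genes and would be lower with fewer.

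The alternatives tried were other background corrections and normalizations, the authors' normalized values, other filters, a fit to only the groups compared, array weights, a trended and robust variance model, another threshold and leaving out each array. The slide of each array is not given in the sources used here, so slide could not be tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every comparison.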

Results

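Liver gene expression was compared in male B6C3F1 mice, a hybrid strain used in tests for carcinogens, long after an exposure early in life. By the study's design text, mice aged 7 days received 3.5 g/L dichloroacetic acid, a by-product of water disinfection, in the water, or 0.06% phenobarbital, or water alone. Exposure lasted 10 weeks and was followed by 90 weeks of water. Phenobarbital served as a known rodent liver mitogen and tumour promoter. The control and DCA groups had 4 mice each and the PB group had 5. Mean raw intensity ranged from 188.6 to 462 among the arrays, and 7141 to 8458 genes were detected per array. The median correlation between arrays was 0.972 within groups and 0.971 between groups, so arrays of one group were about as far apart as arrays of different groups. The first component of variation held 29.9% and the second 21.0% of the variance, and PB replicate 1 lay apart from all other arrays on the second. It was also the lowest array for the means of endothelial (5.53), hepatic stellate (5.31), Kupffer (6.04) and periportal (8.55) markers.

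**Figure D1:**
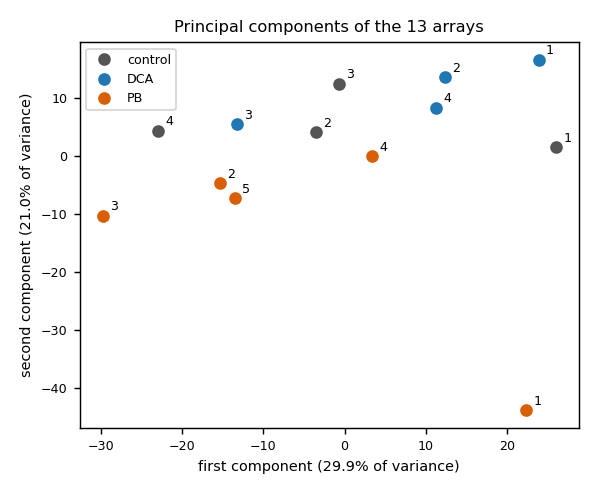
Principal components of the 13 arrays over the tested genes, with each point 1 array, coloured by group and numbered by replicate. The first component (x axis, 29.9% of variance) mixes the groups, and PB replicate 1 lies alone at -43.8 on the second (y axis, 21.0%).

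The comparison of PB with control asked what remained in the liver of the exposure to phenobarbital. Cyp2d12, a cytochrome P450, was higher in PB by 2.76 ± 0.30 on the log2 scale (6.78-fold, adjusted p = 0.00267), at 8.36 ± 0.33 in PB (SD, n = 5) against 5.60 ± 0.76 in control (SD, n = 4). Cyp2b13, a P450 expressed mainly in female liver, was higher by 3.17 ± 0.48 (adjusted p = 0.0283), the serine protease Prss8 by 2.18 ± 0.36 (adjusted p = 0.0472), and Lss, the lanosterol synthase of cholesterol synthesis, by 1.20 ± 0.19 (adjusted p = 0.0283). Metrn was lower, with a log2 difference of -1.18 ± 0.17 (adjusted p = 0.0262), as were Pigt, a subunit of the transamidase that attaches GPI anchors, at -0.99 ± 0.15 (adjusted p = 0.0283), and Bad, a promoter of apoptosis, at -0.71 ± 0.12 (adjusted p = 0.0493). Cyp2b13 was detected on 2 of 4 control arrays, and its control mean of 4.98 lay near the lowest detected levels of the arrays (4.61 to 4.84). These 7 genes, 4 higher and 3 lower, were all that passed in limma among 8431 tested, and each had all PB arrays on one side of all control arrays. At an unadjusted p under 0.05 there were 852 genes, where 421.55 would be expected by chance. With the standard background fit Cyp2b13 differed by 1.60 and Prss8 by 1.05, and only 2 genes passed, Cyp2d12 and Bad, both among the 7, and with the authors' normalized values 5 passed, all among the 7. Leaving out 1 array gave 1 gene without control replicate 3, control replicate 4 or PB replicate 5, 3 genes without control replicate 1 or PB replicate 2 and 13 without PB replicate 4, and leaving out control replicates 2 and 4 together, a choice made after their values were seen, gave 0. The count was 4 without a filter, 2 with only these groups in the fit and 12 among genes detected on all 13 arrays.

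**Figure D2:**
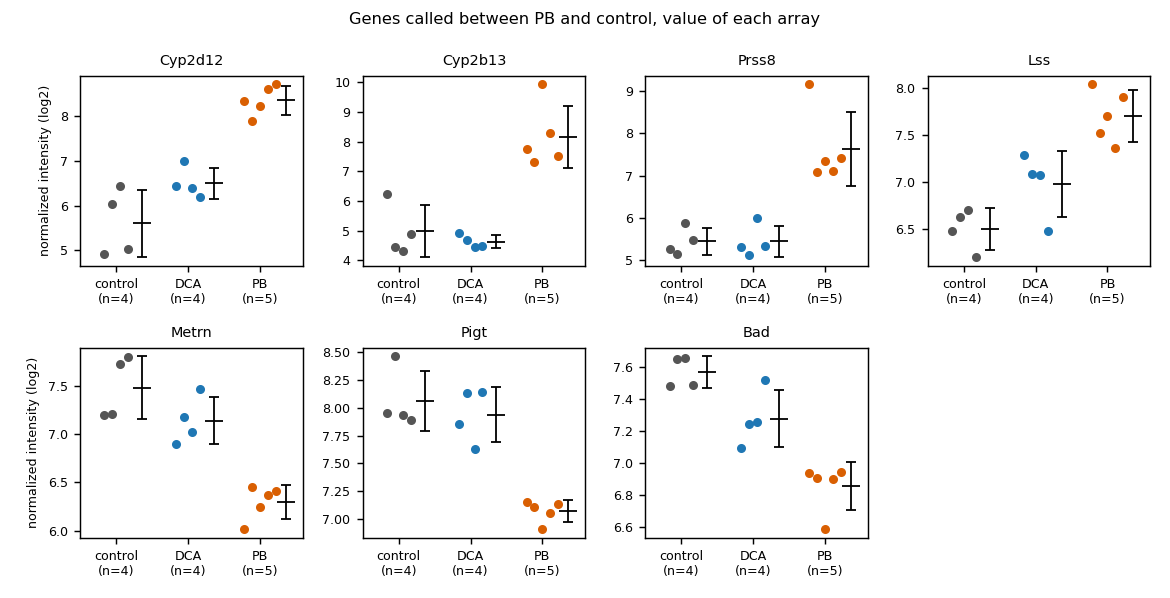
Normalized intensity (log2, y axis) of the 7 genes called between PB and control. Points are single arrays of the 3 groups, bars are group means ± SD. The PB arrays of Cyp2d12 lie above all control arrays, and the Prss8 mean of PB includes PB replicate 1 at 9.15.

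Further genes fell short of the threshold in PB against control and are given as values. Hamp2, a hepcidin gene, differed by 2.86 ± 0.51 (adjusted p = 0.0649), LOC100040592 by 1.53 ± 0.28 (adjusted p = 0.0676), Arrdc3 by 1.69 ± 0.32 (adjusted p = 0.0892) and Endod1 by 0.92 ± 0.18 (adjusted p = 0.0907). On the lower side were Dct at -2.22 ± 0.40 and Tatdn2 at -0.83 ± 0.15 (both adjusted p = 0.0649), with Zfp771 at -0.91 ± 0.17 (adjusted p = 0.0649). Of the 25 single genes fixed beforehand 18 were tested and 0 passed over all genes. Adjusted over the list alone 1 passed, Gdf15, a stress-induced cytokine, with a difference of 0.93 ± 0.22 (limma adjusted p = 0.187 over all genes and 0.0191 over the list alone). Cyp2b10, the P450 that phenobarbital induces most strongly while it is given, lay near background at 4.79 in PB and 4.50 in control, a difference of 0.29 ± 0.14. Igf2 differed by 1.22 ± 0.72 and Glul by 0.93 ± 0.41, and both were highest on PB replicate 1, without which the differences were 0.46 and 0.50.

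Genes of cholesterol synthesis lay higher in PB than in control, 19 of 21 with a median of 0.49, by camera with its preset correlation (adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone 7 passed, against 1 over all genes, among them Lss, Idi1 at 1.02 ± 0.20 and Mvd at 1.88 ± 0.39, which are enzymes of this pathway. PB replicate 1 had the highest mean of this list, and without control replicate 1 its median was 0.81. By camera with its preset correlation 15 of 44 lists passed, 11 higher and 4 lower, and with an estimated correlation 0 passed. In fatty acid and triglyceride synthesis 18 of 21 genes lay higher (adjusted p = 0.294 with an estimated correlation), and adjusted over the list alone 2 passed, the elongase Elovl6 at 1.67 ± 0.36 and the fatty acid synthase Fasn at 0.66 ± 0.18. Among the targets of NRF2, the regulator of antioxidant genes, 19 of 25 lay higher (adjusted p = 0.693 with an estimated correlation), with a median of 0.29, and 0.19 without control replicate 4. Adjusted over the list alone 4 of them passed, including Gsta1 at 2.69 ± 0.58 and Pgd at 1.09 ± 0.30. In the interferon response 29 of 34 genes lay higher (adjusted p = 0.498 with an estimated correlation), with a median of 0.31, and 0.17 without PB replicate 3, and 0 passed adjusted over the list alone. Erythroid markers went the other way, with 8 of 9 lower in PB and a median of -0.75 (adjusted p = 0.294 with an estimated correlation). Adjusted over the list alone 4 of them passed, among them Slc4a1 at -1.20 ± 0.26 and Hbb-b1 at -0.96 ± 0.29. Slc4a1 was detected on only 2 of 5 PB arrays, with a PB mean of 4.68 near the lowest detected levels of the arrays. All 7 platelet markers lay lower, with a median of -0.58 (adjusted p = 0.693 with an estimated correlation), which was -0.11 without control replicate 4. The other lists that passed lay higher for genes of the pericentral zone (median 0.23, and 0.14 without PB replicate 1), tumour associated genes (0.32, and 0.15 without PB replicate 1), CAR targets (0.22, and 0.10 without PB replicate 1), the circadian clock (0.41, and 0.13 without control replicate 2), MHC class II presentation (0.26, and 0.10 without control replicate 1), p53 targets (0.11, and 0.21 without control replicate 2) and female-biased genes (0.10, and -0.02 without PB replicate 3). They lay lower for the acute phase response (-0.26, and -0.14 without control replicate 2) and male-biased genes (-0.23, and -0.07 without PB replicate 1). For these lists the test gave adjusted p = 0.294 with an estimated correlation for p53 targets, adjusted p = 0.716 for male-biased genes and adjusted p = 0.693 for the rest. Leaving out 1 array moved the median of 13 of the 15 lists by over 1.5 times. The directional test of fry passed 0. An exact permutation test of list means can give no p below 0.00794 here. It could therefore pass no list over the 44 if only 1 was low. It gave 4 lists with an unadjusted p under 0.05 and a smallest adjusted p of 0.262. The mixed test of fry, which asks for changes in either direction and sets the list against no other genes, passed 5 lists, namely female-biased genes, cholesterol synthesis, NRF2 targets, CAR targets and fatty acid synthesis. Cyp2b13 is in both the female-biased and the CAR list and is the only called gene of each, so these lists are not independent. Of 100 splits of the same arrays, 26 gave as many lists as the real one, so the number of lists is no larger than regrouped arrays often give.

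The comparison of DCA with control asked the same of dichloroacetic acid. No gene passed, with 0 of 8431 in limma and a smallest adjusted p of 0.995. At an unadjusted p under 0.05 there were 370 genes, fewer than the 421.55 expected by chance, and the groups did not overlap in 2.41% of genes, where chance gives 2.86%. The count stayed at 0 with the standard background fit and with the authors' normalized values. Some of the genes with the smallest p are given as values. Herpud1, of the degradation of misfolded proteins in the endoplasmic reticulum, differed by 0.91 ± 0.22, Plekhf1 by 0.68 ± 0.18, Klf13 by 1.05 ± 0.29, the deacetylase Sirt2 by 0.58 ± 0.16 and Thrsp, a regulator of fat synthesis, by 1.78 ± 0.49. On the lower side were Arglu1 at -0.57 ± 0.13, AA409316 at -0.75 ± 0.20, Zkscan6 at -0.54 ± 0.15, Camkk2 at -0.51 ± 0.15 and Fadd at -0.45 ± 0.14. Gstz1, the enzyme that metabolises dichloroacetic acid, was at 12.4 in both groups, with a difference of -0.03 ± 0.12. Cyp4a14, a PPARA target, differed by -2.58 ± 0.94 (adjusted p = 0.995). In simulated data 73.1% of changes of 1 on the log2 scale were recovered for this comparison. There 67 genes were changed by 0.5, 67 by 1 and 66 by 2. With fewer changed genes the adjustment is stricter, so changes of 1 could also be missed here, and smaller ones often.

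The 15 tested genes of the circadian clock lay higher in DCA than in control, with a median of 0.46, by camera with its preset correlation (adjusted p = 0.649 with an estimated correlation), but without control replicate 2 only 11 did and 4 lay lower. They included Per2 at 1.07 ± 0.41 and Dbp at 1.48 ± 0.68, and 0 passed adjusted over the list alone. Control replicate 2 had the lowest Dbp of all arrays, at 7.38, and without it the Dbp difference was 0.57 and the median of the list 0.25. Control replicate 4 had the next lowest Dbp, at 9.96, and without it alone the Dbp difference was 1.43 and the median 0.43. Control replicate 2 was the highest array for the means of neutrophil (7.45), Kupffer (7.59) and acute phase (10.6) genes. By camera with its preset correlation 11 lists passed, 6 higher and 5 lower, and with an estimated correlation 0 passed. In oxidative phosphorylation 47 of 61 genes lay higher, with a median of 0.15 (adjusted p = 0.649 with an estimated correlation). Among genes of the unfolded protein response 16 of 20 lay higher (adjusted p = 0.649 with an estimated correlation), with a median of 0.40, and 0.22 without control replicate 4. Herpud1 passed adjusted over the list alone, the chaperone Hyou1 was at 1.04 ± 0.33, and Atf4 was on the lower side at -0.38 ± 0.13. Of 34 interferon response genes 29 lay lower (adjusted p = 0.649 with an estimated correlation), among them Rsad2 at -1.13 ± 0.38, with a median of -0.21, and -0.32 without control replicate 3. Of 9 erythroid markers 7 lay lower (adjusted p = 0.594 with an estimated correlation), and 5 passed adjusted over the list alone, including Slc4a1 at -1.06 ± 0.28 and Hbb-b1 at -1.12 ± 0.30. Over all genes both had a limma adjusted p of 0.995. Slc4a1 was detected on 3 of 4 DCA arrays, with a DCA mean of 4.82 near the lowest detected levels of the arrays. The other lists that passed lay higher for heat shock genes (median 0.31, and 0.17 without control replicate 4), male-biased genes (0.27, and 0.12 without control replicate 4) and endothelial markers (0.26, and 0.15 without control replicate 4). They lay lower for platelet markers (-0.69, and -0.07 without control replicate 4), neutrophil markers (-0.56, and -0.14 without control replicate 2) and female-biased genes (-0.21, and -0.05 without control replicate 1). For these lists the test gave adjusted p = 0.790 with an estimated correlation for male-biased genes, adjusted p = 0.852 for endothelial markers and adjusted p = 0.649 for the rest. Leaving out 1 array moved the median of 9 of the 11 lists by over 1.5 times. The directional and the mixed test of fry passed 0. An exact permutation test of list means can give no p below 0.0286 here. It could therefore pass no list over the 44 if only 1 was low. It gave 0 lists with an unadjusted p under 0.05 and a smallest adjusted p of 0.786. Of the 35 splits of these arrays 16 gave as many lists as the real one, and without control replicates 2 and 4 together 7 lists passed.

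DCA and PB were compared directly to test where the treatments differed. In limma 9 genes passed. The genes lower in DCA were Cyp2b13 at -3.53 ± 0.48 (adjusted p = 0.0198), Prss8 at -2.18 ± 0.36, LOC100040592 at -2.14 ± 0.28, Cyp2d12 at -1.86 ± 0.30, the isomerase Idi1 of cholesterol synthesis at -1.41 ± 0.20 and Endod1 at -1.19 ± 0.18. Cyp2b13 was detected on 2 of 4 and Idi1 on 3 of 4 DCA arrays, with DCA means of 4.63 and 4.71, inside the range of the lowest detected levels. Higher in DCA were Srd5a1, a steroid reductase, at 1.57 ± 0.27, Zfp771 at 0.96 ± 0.17 and Pigt at 0.87 ± 0.15. Cyp2b13, Cyp2d12, Pigt and Prss8 had also passed between PB and control. At an unadjusted p under 0.05 there were 1224 genes. With the standard background fit Cyp2b13 differed by -1.66, Prss8 by -1.05, Srd5a1 by 0.72, Zfp771 by 0.36 and Idi1 by -0.24, and 1 gene passed, Cyp2d12, and with the authors' normalized values 2 passed, both among the 9. The count was 305 with array weights, 16 with only these groups in the fit and 0 without a filter. With other background corrections or normalizations, the standard fit included, it ranged from 1 to 5. It was 0 without DCA replicate 1, 2 or 4, 3 without PB replicate 5, 4 without PB replicate 3 and 5 without PB replicate 1. Ubd, an interferon-induced gene, differed by -3.10 ± 0.61 (adjusted p = 0.0806) and Mvd by -2.11 ± 0.39 (adjusted p = 0.0618). Ubd was detected on 2 of 4 DCA arrays, with a DCA mean of 4.84 near the lowest detected levels. The F test over the groups passed 9 genes, 1 with the standard background fit, 52 with array weights and 0 without a filter.

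**Figure D3:**
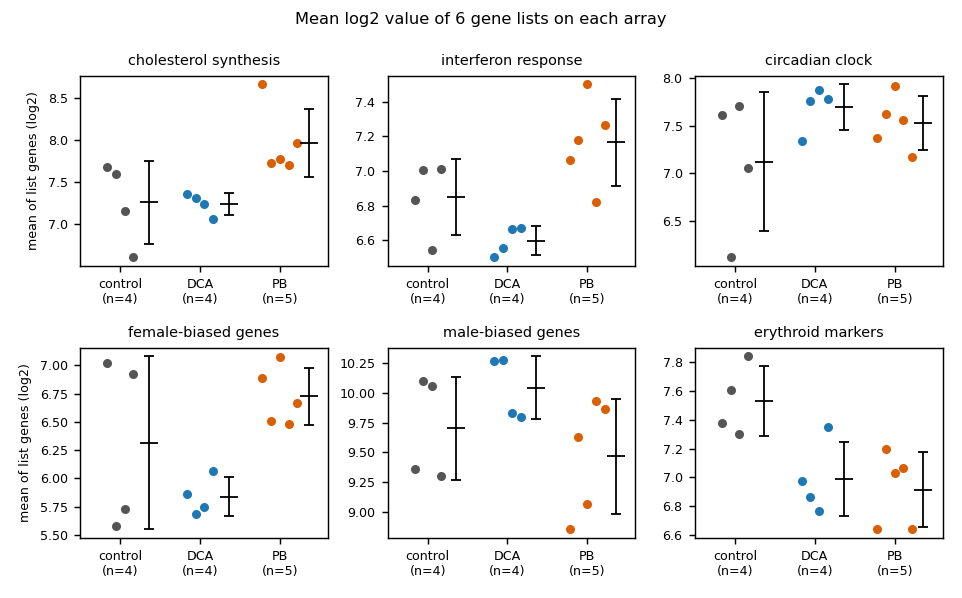
Mean log2 value of the tested genes of 6 lists (y axis) on each array. Points are arrays of the 3 groups, bars are group means ± SD. Groups overlap in the circadian clock list, where control replicate 2 is the lowest array.

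In the interferon response 33 of 34 genes lay lower in DCA than in PB, with a median of -0.52, by camera with its preset correlation (adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone 15 passed, 14 lower, such as Usp18 at -1.60 ± 0.33 and Ifit3 at -1.05 ± 0.23, and 1 higher, Ifi35 at 0.50 ± 0.19, the only one of the 34 to lie higher, which was picked for naming after its value was seen. By camera with its preset correlation 8 lists passed, 3 higher and 5 lower in DCA, and with an estimated correlation 0 passed. In cholesterol synthesis 17 of 21 lay lower (adjusted p = 0.577 with an estimated correlation), and 10 passed adjusted over the list alone. Of 9 genes of MHC class II presentation 8 lay lower, including H2-Aa at -1.11 ± 0.26 (adjusted p = 0.577 with an estimated correlation for the list). Of 25 male-biased genes that depend on growth hormone 24 lay higher in DCA, including Serpina3k at 0.72 ± 0.15 and Cyp7b1 at 0.92 ± 0.27 (adjusted p = 0.577 with an estimated correlation for the list). Control replicates 1 and 4 and DCA replicates 3 and 4 lay within the range of PB for the mean of these genes. Of 19 female-biased genes 16 lay lower, including Cyp2b9 at -3.31 ± 0.83 (adjusted p = 0.561 with an estimated correlation for the list), with a median of -0.47, and -0.31 without PB replicate 3. The other lists that passed lay higher in DCA for oxidative phosphorylation (median 0.23) and the unfolded protein response (0.37, and 0.25 without DCA replicate 1), and lower for tumour associated genes (-0.46, and -0.30 without PB replicate 1). For these lists the test gave adjusted p = 0.561 with an estimated correlation for oxidative phosphorylation and adjusted p = 0.577 for the rest. The directional test of fry passed 0. The exact permutation test, with the same limit of 0.00794, gave 6 lists with an unadjusted p under 0.05, of which 3 were at that limit. Its smallest adjusted p was 0.116, so 0 lists passed. The mixed test of fry passed 4 lists, namely the interferon response, female-biased genes, cholesterol synthesis and CAR targets, of which the female-biased and the CAR list share Cyp2b13. Of 100 splits 71 gave as many lists.

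The log2 differences of DCA and of PB from control had a correlation of 0.23 across genes, which are not independent replicates. Unchanged groups gave 0.50 on average, with 95% of draws between -0.26 and 0.92. In each draw both treatment groups shared a control group that was itself drawn, and an array could be drawn for several groups. The covariance was 0.0166, against 0.0308 in unchanged groups. With 2 controls given to each treatment the correlation was between -0.34 and 0.0013 over 6 splits. At an unadjusted p under 0.05, 31 genes lay higher and 45 lower in both, where independent lists would share 8.93 and 9.72. A response shared by the treatments was not detectable beyond what shared controls give in these draws. Their range is so wide that a shared response could lie inside it, so the test cannot decide whether there was one.

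The median SD over genes was 0.26 in control, 0.22 in DCA and 0.26 in PB. The mean distance of an array from its group was 0.37 ± 0.06 in control (SD, n = 4), 0.29 ± 0.07 in DCA (SD, n = 4) and 0.35 ± 0.12 in PB (SD, n = 5). Exact permutation tests gave p = 0.171 for DCA against control, p = 0.825 for PB against control and p = 0.476 for DCA against PB, with a smallest adjusted p of 0.514 over 3 tests. For DCA against control the smallest p that the arrays allow is 0.0286, or 0.0857 adjusted over 3 tests if it alone is low, so that test says little about a difference in spread.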

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

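Tests of array signal and of tumour genes on PB replicate 1, of collection time, of PB replicate 1 in the sex-biased lists and of Cyp2b10 were chosen after the values had been seen. A far array was looked for in 111 groups of values and found in 11, where chance gives about 5.55.

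PB replicate 1 lay apart from the other 12 arrays, at -43.8 on the second component where the nearest PB array was at -10.3, and among the genes left out of the tests 19 lay above all controls by over 2 on it, against at most 4 on a control array. It had the highest Prss8 (9.15), the highest Idi1 (6.59), and the highest means of cholesterol synthesis (8.66) and of pericentral genes (9.61, next of all arrays 8.35) in its group, and it was the lowest of all arrays for endothelial (5.53, next 6.25), stellate (5.31, next 5.84), Kupffer (6.04, next 6.40) and periportal (8.55, next 9.04) markers. A weaker array is argued against, since its signal over background of 2.36 lies inside the range of the others (1.99 to 4.10), and so is exocrine pancreas, whose markers lay a median of -0.11 from the highest other array (5 of 23 above it), although Pnliprp1 was high at 10.1. Tumour tissue in this sample is a candidate explanation that the values allow: 13 of 52 tumour associated genes, such as Igf2, Gpc3, Afp and H19, were highest here by over 1, against 0.658% of all other genes (Igf2 at 9.39 against at most 6.54 elsewhere; one-sided Fisher's exact test, p = 4.38e-17, over genes that are not independent), but PB replicate 5 also had a high mean of these genes (7.33, against 7.81 here and 6.30 to 6.80 on the remaining arrays), and no histology was used here.

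Clock genes lay higher in DCA than in control by a median of 0.46. Collection of control replicate 2 at another time of day could contribute, since without it the median was 0.25, a little over the bound set for calling this the cause, the mean fell from 0.57 to 0.24 and 4 of 15 genes lay lower. Control replicate 4 had the next lowest clock mean of all arrays (7.05), but without it alone the median was 0.43. Control replicate 2 was the highest array for neutrophil (7.45, next 6.59), Kupffer (7.59, next 6.99), senescence (7.45, next 7.07) and acute phase genes (10.6, next 10.5), so that another state of this animal stays open, untested. With all arrays the median was 0.45 with cyclic loess and 0.44 with median scaling, and 0.27 in the authors' normalized values, where the spread of all genes is smaller as well (median SD of control 0.137 against 0.261), so that value does not single out clock genes, although the bound set beforehand for excluding normalization was not met. No collection time is given in the sources used here, so neither explanation is decided.

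Female-biased genes lay higher and male-biased genes lower in PB than in DCA, but the unexposed controls 1 and 4 had means inside the range of PB for both lists, female-biased 7.02 and 6.93 (PB 6.48 to 7.08) and male-biased 9.36 and 9.30 (PB 8.85 to 9.93). DCA replicates 3 and 4 also lay inside the PB range for male-biased genes, at 9.83 and 9.80 (exact permutation test of DCA against PB, p = 0.103). For female-biased genes no DCA array did. Female animals are argued against: Xist was detected on no array, and the lowest PB array lay -0.37 from the lowest other array for the Y-linked gene Eif2s3y. PB replicate 1 might carry part of it, since 70.2% of the male-biased and 97.4% of the female-biased difference was left without it. For lasting induction by phenobarbital, the Cyp2b10 difference of 0.29 ± 0.14 met the bound set for arguing against it. However, Cyp2b10 lay near background and was detected on only 3 of 5 PB arrays, so this 1 dim gene was not taken to decide. Cyp3a11 and Cyp2c55, also among the single genes fixed beforehand, differed between PB and control by 0.09 ± 0.73 and 0.42 ± 0.53. Cyp2b13, higher in PB than in control by 3.17 ± 0.48, belongs to both the CAR target and the female-biased list. These lists are therefore not separate evidence. A hormonal or tissue difference between the groups was not tested.

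Other far arrays were control replicate 2 for Pigt (8.46), PB replicate 3 for Bad (6.59), control replicate 4 for the mean of pericentral genes (7.54), DCA replicate 1 for tumour associated genes (6.33), and DCA replicate 3 for CAR targets (8.15) and MHC class II (6.23).

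The same arrays were regrouped. Of 100 splits only the real one gave as many as the 7 genes of PB against control (highest other 1). The same held for the 9 genes of DCA against PB (1 of 100, highest other 1). Such counts were therefore rare among regrouped arrays in the main fit, which does not test any single gene. For the F test 4 of 100 splits gave as many as 9 genes, and 1 gave 208. This points to a structure of the arrays that the groups follow only in part. That split put PB replicates 2, 3 and 5 with control replicate 4 and DCA replicate 3, the lowest arrays on the first component (-29.8 to -13.3, next -3.53). Mean raw intensity was 250 ± 65 in PB, 311 ± 78 in control and 331 ± 108 in DCA (SD over arrays). Whether array signal contributes to the PB differences was not tested. With 0 genes in DCA against control the number of splits as large (35 of 35) is fixed and tests nothing (highest other 1). Chance was not excluded for the lists. The 11 lists of DCA against control were reached by 16 of 35 splits (highest other 15), the 15 of PB against control by 26 of 100 (highest other 24) and the 8 of DCA against PB by 71 of 100 (highest other 16).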

How the results depend on the processing

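The fit of the background on all rows, the keeping of bright genes, the joint removal of control replicates 2 and 4 and the list and gene values without single arrays beyond the counts were chosen after seeing the data. No called gene changed direction under any alternative. Cyp2d12 in PB against control passed under all 20 alternatives chosen beforehand and 22 of 23 in all, and missed the threshold only without control replicates 2 and 4 (adjusted p = 0.0816, the highest of a range from 0.000614). Of 20 alternatives, Metrn passed under 16, Pigt under 13, Lss under 10, and Bad and Prss8 under 7 each, and Cyp2b13 passed under 10 of 19. In DCA against PB, LOC100040592 passed under 16 of 20, Endod1 under 12, Cyp2d12 and Prss8 under 9 each, Srd5a1 under 7, Pigt under 5 and Zfp771 under 4, and Cyp2b13 passed under 12 and Idi1 under 11 of 19. The log2 differences of PB against control ranged from 1.60 to 3.04 for Cyp2d12, 1.60 to 3.60 for Cyp2b13, 1.05 to 2.32 for Prss8, 0.74 to 1.29 for Lss, -1.27 to -0.65 for Metrn, -1.08 to -0.68 for Pigt and -0.78 to -0.45 for Bad. Those of DCA against PB ranged from -3.74 to -1.66 for Cyp2b13, -2.36 to -1.05 for Prss8, -2.31 to -1.99 for LOC100040592, -2.03 to -1.23 for Cyp2d12, -1.59 to -0.24 for Idi1, -1.32 to -0.72 for Endod1, 0.72 to 1.76 for Srd5a1, 0.36 to 1.02 for Zfp771 and 0.59 to 0.97 for Pigt. Except for LOC100040592, the smallest came without background correction or with the background of all rows. DCA against control gave 0 genes under each alternative. Except where the construction shows it (fewer arrays, another threshold, another gene set), the cause was not tested. All probes of a gene could not be tested because the table holds 1 row per gene, and slide was not run because the sources used here give none. No paired analysis was possible because replicate numbers only follow the order of the samples. Signal over background, from 1.99 to 4.10, limits dim genes such as Cyp2b10.

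Gene counts moved as follows. In DCA against PB 3 genes passed by normexp without detection p-values, 2 without background correction, 4 with cyclic loess, 5 with median scaling, 2 with the authors' values, 0 without a filter, 1 with the background of all rows, 16 with only these groups in the fit, 305 with array weights and 40 at an adjusted p under 0.10. In PB against control 4 passed without a filter, 12 when detected on all 13 arrays, 2 with the background of all rows, 2 with only these groups in the fit, 14 at an adjusted p under 0.10 and 0 without control replicates 2 and 4. The F test gave 1 by normexp without detection p-values, 1 without background correction, 1 with the authors' values, 0 without a filter, 1 with the background of all rows, 52 with array weights and 19 at an adjusted p under 0.10. Leaving out each array gave 0 to 0 for DCA against control, 1 to 13 for PB against control (1 without control replicates 3 or 4 or PB replicate 5, 3 without control replicate 1 or PB replicate 2, 13 without PB replicate 4), 0 to 13 for DCA against PB (0 without DCA replicates 1, 2 or 4, 3 without PB replicate 5, 4 without PB replicate 3, 5 without PB replicate 1) and 1 to 9 for the F test (1 without DCA replicate 2, 2 without PB replicate 2, 3 without control replicate 3 or PB replicates 1, 3 or 5, 4 without DCA replicate 4, 5 without control replicate 4).

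Of the lists, 0 passed in each comparison with an estimated correlation and 0 with fry's directional test, while its mixed test passed 5 in PB against control, 4 in DCA against PB and 0 in DCA against control. In DCA against control 7 passed without control replicates 2 and 4, in PB against control 9 when detected on all 13 arrays, and in DCA against PB 14 with median scaling and 5 when detected on all 13 arrays. Leaving out each array gave 8 to 14 lists for DCA against control, 12 to 16 for PB against control and 8 to 15 for DCA against PB (15 without PB replicate 3). The median of 9 of 11, 13 of 15 and 3 of 8 called lists, in the same order, moved by over 1.5 times when 1 array was left out, and 1, female-biased genes in PB against control, turned.

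The median SD of control, DCA and PB was 0.171, 0.144 and 0.168 by normexp without detection p-values, 0.132, 0.111 and 0.130 without background correction, 0.137, 0.113 and 0.134 with the authors' values and 0.123, 0.116 and 0.123 without a filter.

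Genes that had not passed reversed in places. Without control replicates 2 and 4, DCA against control gave S100a8 0.61, S100a9 0.22, Mmp9 0.062, Cxcl4 0.15, Gp9 0.084, Gp5 0.00175 and Cdkn1a 0.037, and PB against control gave Dbp -0.12 and Cxcl4 0.49. Gstz1 in DCA against control ran from -0.086 to 0.011 when single arrays were left out, above 0 without control replicate 2 (0.011) and DCA replicate 1 (0.0084).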
